A study of Homo sapiens with 39 samples.

How the data were processed

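RNA was sequenced from 39 libraries of 2 human leukaemia cell lines. The MOLM-13 libraries came from a clone with inducible Cas9 and formed 3 batches, and the MV4;11 libraries formed batch 4. Batch 1 held 15 libraries taken 3 or 5 days after doxycycline was added, with guide RNAs against ENL (gene symbol MLLT1; guides sgENL1 and sgENL5), against its relative AF9 (gene symbol MLLT3; sgAF9) or against GFP as a control. Every guide and day had 2 libraries, except sgGFP at day 3, which had 1. Batch 2 held 10 libraries at 4 days, 2 per group: a luciferase guide with an empty vector (sgLuc), and an ENL guide with an empty vector, wild-type ENL (WT) or ENL carrying the change F59A or Y78A. Batch 3 held 8 libraries, 2 per group: sgGFP or sgENL cells treated for 24 h with DMSO or with 50 nM JQ1, an inhibitor of BET bromodomain proteins. Batch 4 held 6 libraries of MV4;11 cells taken 6 days after infection with a short hairpin against ENL (shENL) or a non-targeting hairpin (shNT), 3 each.

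Per the labels' protocols, RNA was purified on RNeasy columns and libraries were made with a TruSeq mRNA kit of version 2, which keeps no strand, and 15 PCR cycles. Per the submitters' processing notes, bases were called with CASAVA 1.8.2, reads were aligned to hg19 with TopHat2, and reads per gene were counted with HTSeq 0.6.0. The same notes name DESeq2 and edgeR without saying what each was used for. The deposited tables hold 1 count per gene and library, 57820 genes in batches 1 to 3 and 57736 in batch 4. All 57736 gene identifiers of the MV4;11 table were found in the MOLM-13 tables, which also gave the gene symbols, and 0 count columns were left unused. The kit keeps no strand, so genes that overlap on opposite strands share reads. Genes with near-identical copies, such as NCF1, the HLA class II genes, histone genes and ribosomal protein genes, may also share reads, and their values are uncertain for that reason.

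Each batch was fitted alone with edgeR 4.0.16 in R 4.3.3: genes were kept by the default expression filter, libraries were scaled by trimmed means of M values, and a quasi-likelihood model with robust dispersions held 1 coefficient per group. The filter left 17610, 16212, 16408 and 17441 genes in batches 1 to 4. Depth was 30.0 to 87.2 M counts (M for mega) per library in batch 1, 35.2 to 60.2 in batch 2, 26.2 to 54.5 in batch 3 and 75.4 to 115 in batch 4. The common biological coefficient of variation was 0.0515, 0.0942, 0.0978 and 0.158, on 7, 5, 4 and 4 residual degrees of freedom. A gene was called when its adjusted p (Benjamini-Hochberg, over all genes tested in the comparison) was 0.05 or less. Fold changes are log2 values of the fitted model. The value in parentheses after a fold change is its standard error, worked back from the fold change and the F statistic of its test. A prior count of 2 entered only the log levels used to check pairing and whether groups overlapped. Levels are counts per M counts of the library (CPM) given as mean ± SD over libraries. The library total used for them was that of the kept genes, multiplied by the scaling factor of the library. The comparison with ENL guides weighted both guides equally, and the interaction was the JQ1 effect in sgENL cells less that in sgGFP cells. The labels do not state whether the libraries of a group came from separate cultures, so every p-value measures only the spread between these samples.

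The 15 comparisons and 16 gene lists were fixed before the data were examined. The lists were genes of the elongation complexes around ENL (26 genes), the HOXA-MEIS1 leukaemia program (32), MYC targets (52), monocyte and macrophage genes (34), granulocyte precursor genes (16), stem and progenitor genes (23), p53 targets (32), interferon response genes (36), cell cycle genes (34), genes raised by BET inhibitors (12), sterol synthesis genes (20), integrated stress response genes (22), lymphocyte genes (14), erythroid and megakaryocyte genes (16), epithelial and fibroblast-like genes (11) and ribosomal protein genes (87). Each list was tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, and again with a correlation estimated from the data and with fry. Of the 240 tests, 107 passed with the preset correlation, 3 of these with the estimated correlation and 72 with fry. Sets taken from day 5 of batch 1 were tested in the other batches in the same way, and overlaps were tested with Fisher's exact test. A panel of 14 genes (MLLT1, MLLT3, HOXA9, HOXA10, MEIS1, MYB, MYC, BCL2, CDK6, FLT3, HEXIM1, CD14, ITGAM and CDKN1A) was read in every comparison, except CD14 in batch 3, where the filter removed it. Other genes were named by rule: the 10 largest rises and falls among called, well expressed genes whose groups did not overlap, and up to 4 members of each list that passed. Lists of MHC class II, hypoxia and immediate early genes, and all comparisons beyond the 15, were chosen after seeing the data.

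The pipeline was tested on simulated data in which 200 genes were changed in each comparison. It found 8.96% to 98.5% of 1.5-fold changes, 71.6% to 100% of 2-fold changes and 97% to 100% of 4-fold changes, with at most 19 false calls. The lowest shares at 1.5-fold and 2-fold belonged to the interaction. Libraries were checked for pairing by replicate number, after group means were removed. Libraries of the same number correlated at 0.203 to 0.455 over 20 pairs in batch 2. The correlations were -0.097 to 0.083 in batch 1, -0.085 to 0.095 in batch 3 and 0.022 to 0.226 in batch 4. In a group of 2 libraries, the remainders of the 2 mirror each other. Each correlation in batches 1 to 3 was therefore counted for both numbers, and the 20 pairs hold repeated values. By the rule set for this check, the numbers paired libraries in batch 2 only, and counts from a fit with a block per replicate number are given beside the batch 2 results. Of 22 pairs of replicate libraries, 0 were identical, and their chi-square per degree of freedom was 3.43 to 180. Alternatives were scaling by relative log expression (RLE), no filter, a replicate block, DESeq2 1.42.0, a fit of only the groups compared, each ENL guide alone, and leaving out each library in turn. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The supplied annotation is on another genome build than the counts and was used only for exon lengths, matched by gene identifier.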

Results

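ENL reads acetylated histones through its YEATS domain and binds the machinery of transcription elongation. RNA levels were compared in cells of 2 acute myeloid leukaemia lines that received guide RNAs or a short hairpin against ENL, a guide against AF9, constructs of ENL as wild type or with a changed YEATS domain, or JQ1 as well.

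With the ENL guides at day 5, MYC, a growth-driving transcription factor, fell 1.85-fold (log2 -0.89 (0.05), adjusted p = 5.66e-13), from 397 ± 12 CPM in sgGFP cells to 215 ± 4.79 CPM. These are means of 2 and 4 libraries. The granule enzyme gene MPO fell 2.59-fold to 23.4 ± 2.86 CPM from 60.2 ± 4.35 CPM. From day 3 to day 5 MPO changed by log2 0.57 in sgGFP cells, with 1 library at day 3, and by -0.22 with the ENL guides. The myeloid calcium-binding genes S100A8 and S100A9 rose 2.14-fold (to 34.8 ± 2.68 CPM) and 1.79-fold, and ITGAM, which encodes the integrin CD11b, rose 1.43-fold. Of the sterol synthesis genes 18 of 19 fell (list adjusted p = 0.144 with an estimated correlation), genes that rose from day 3 to day 5 in sgGFP (median 0.69) and sgAF9 cells (0.39). The HOXA-MEIS1 program did not pass as a list.

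The target itself, MLLT1, fell to 29.8 ± 9.43 CPM from 41.4 ± 6.77 CPM (log2 -0.53 (0.08), adjusted p = 7.15e-05), and the guides differed in this. MLLT1 stood at 37.8 ± 1.47 CPM with sgENL1 and 21.8 ± 3.24 CPM with sgENL5 (n = 2 each), against 51.9 ± 0.831 CPM at day 3 and 38.2 ± 3.54 CPM at day 5 in sgAF9 cells. Compared directly, sgENL5 cells had less MLLT1 RNA than sgENL1 cells (log2 -0.79 (0.10), adjusted p = 0.000242), and 82 genes differed between the guides. Guide-directed cuts need not lower the RNA, so the MLLT1 level does not measure how much protein was lost. MLLT3, the relative AF9, was not called (log2 -0.20 (0.07), adjusted p = 0.0567).

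At day 5, 3158 genes were called, 1570 higher and 1588 lower, of which 48 rose and 178 fell by 2-fold or more. Among the largest falls were RGS1, a regulator of G protein signalling (6.02-fold, to 10.5 ± 2.68 CPM from 62.6 ± 31.3 CPM), PFKFB4 (3.64-fold), the receptor gene TNFRSF19 (2.67-fold), DDN (2.66-fold), MPO, and CBS, an enzyme of cysteine synthesis (2.25-fold). The largest rises were the cyclin gene CCNA1 (2.74-fold, to 15.5 ± 2 CPM from 5.6 ± 0.283 CPM), S100A8, BEX1 (2.09-fold) and the hypoxia factor EPAS1 (2.08-fold). Within the panel, CDKN1A (log2 0.26), HEXIM1 (0.19) and MYB (0.16) rose slightly, and HOXA9 fell slightly (log2 -0.16, adjusted p = 0.0382, a call not kept in all omissions of 1 library). MEIS1 (log2 0.13, adjusted p = 0.0872) and HOXA10 (log2 -0.14, adjusted p = 0.08) were not called, nor were BCL2, CDK6 and FLT3.

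Sterol genes fell in 18 of 19 cases and rose in 0 (list median log2 -0.44, adjusted p = 1.91e-19, or 0.144 with an estimated correlation), with MVK 1.41-fold lower. The 22 integrated stress response genes showed 14 falls and 0 rises (median -0.25, adjusted p = 1.79e-09, or 0.144 with an estimated correlation), with TRIB3 1.68-fold lower at 31.7 ± 0.843 CPM. Of 34 cell cycle genes 13 fell and 0 rose, 15 when adjusted over the list alone (median -0.14, adjusted p = 1.45e-07, or 0.333 with an estimated correlation), such as UHRF1 (1.33-fold) and MCM2 (1.28-fold). MYC targets fell in 19 of 52 cases and rose in 1, with 22 falls when adjusted over the list alone (median -0.13, adjusted p = 1.67e-07, or 0.473 with an estimated correlation), as for UNG (1.37-fold). Among 28 monocyte genes, 10 rose and 1 fell (median 0.19, adjusted p = 6.8e-05, or 0.144 with an estimated correlation), and CD36, a scavenger receptor gene, rose 1.58-fold. Among 30 p53 targets, 13 rose and 3 fell (median 0.15, adjusted p = 0.000201, or 0.144 with an estimated correlation), with CD82 1.81-fold higher.

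The other 10 lists did not pass at day 5. The HOXA-MEIS1 program had 5 genes higher and 4 lower of 31, or 10 and 8 when adjusted over the list alone (adjusted p = 0.662). Granulocyte precursor genes had 4 higher and 4 lower of 13 (median 0.07, test direction down, adjusted p = 0.489), stem and progenitor genes 0 and 4 of 12 (adjusted p = 0.15), and interferon genes 6 and 5 of 34 (adjusted p = 0.294). The elongation complexes had 2 higher and 4 lower of 26 (adjusted p = 0.36), and the genes raised by BET inhibitors 3 and 1 of 11 (median 0.02, mean -0.09, test direction up, adjusted p = 0.595). Ribosomal protein genes had 3 higher and 1 lower of 84 (adjusted p = 0.294). The lymphocyte (0 and 1 of 7, adjusted p = 0.822), erythroid (0 and 1 of 4, adjusted p = 0.822) and epithelial genes (2 and 1 of 6, adjusted p = 0.429) were few. Without sgGFP replicate 1 the count of called genes was 2008, and without sgGFP replicate 2 it was 1500. In every omission 44 of 50 named calls were kept, and PFKFB4 was lost without sgGFP replicate 1.

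**Figure D1:**
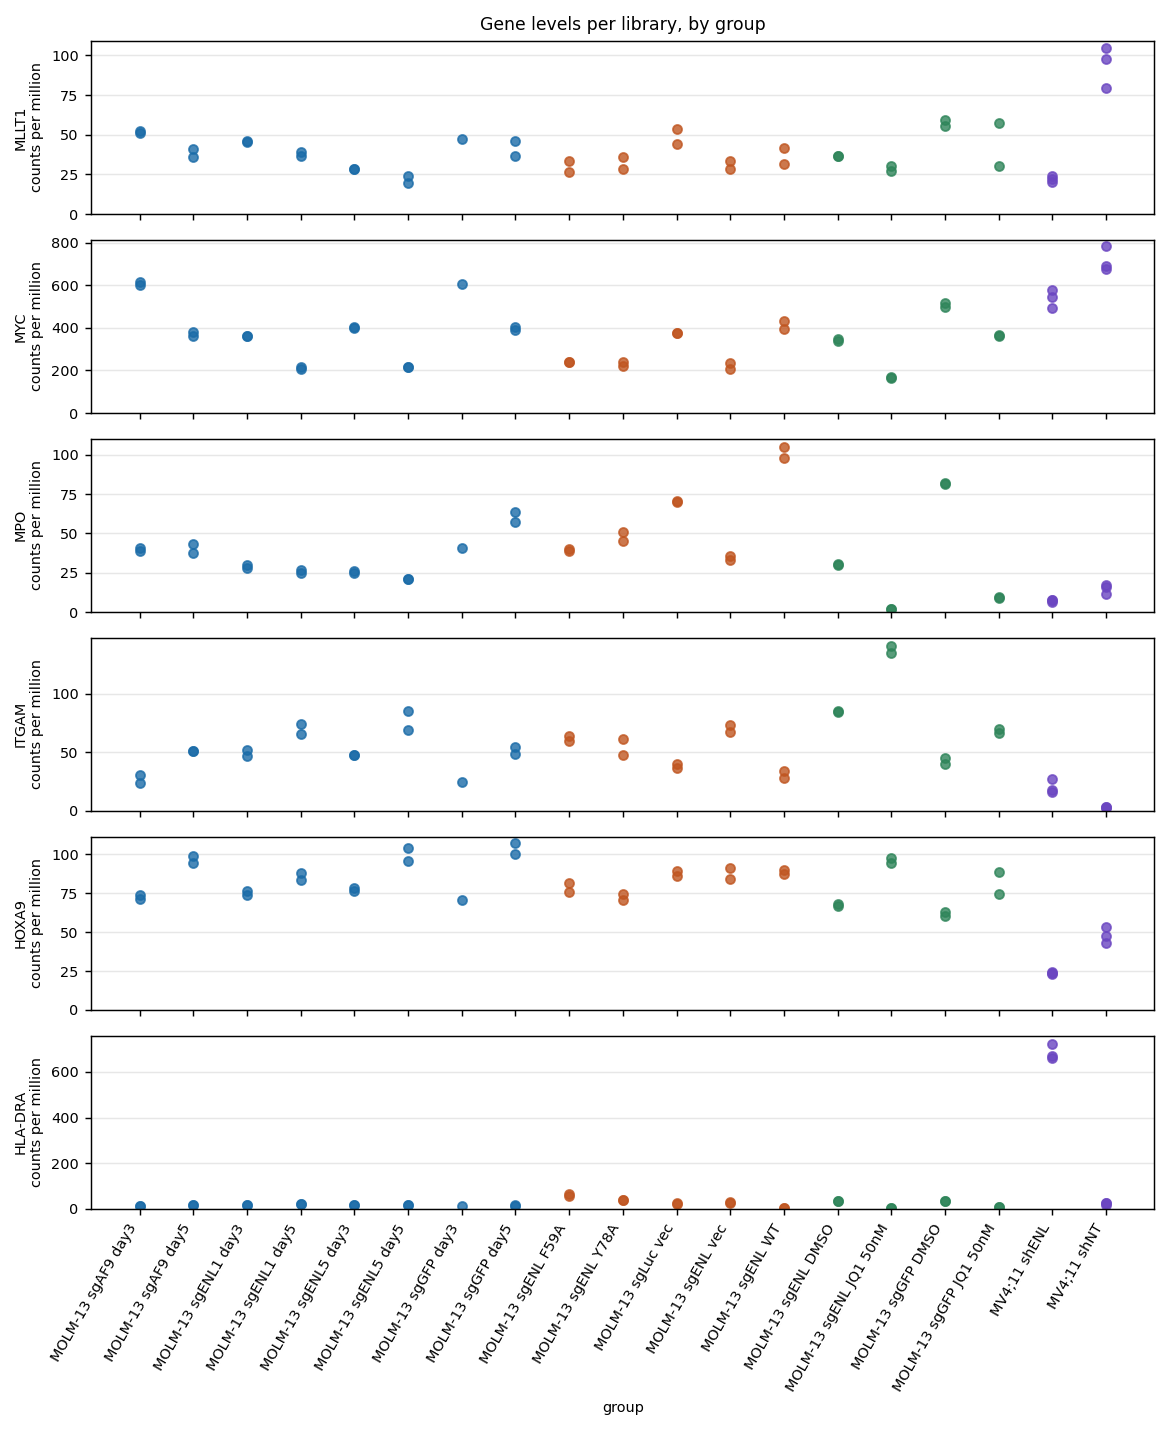
Each point is the CPM of a gene in 1 library, with groups along the horizontal axis, colour for the batch and each vertical axis starting at 0. At day 5, MYC was 215 ± 4.79 CPM with the ENL guides (n = 4) and 397 ± 12 CPM with sgGFP (n = 2).

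At day 3 MYC had already fallen 1.59-fold (log2 -0.67 (0.06), adjusted p = 1.1e-07), to 383 ± 23.9 CPM (n = 4) from 608 CPM in the only sgGFP library of that day. The myeloid genes ITGAM and CSF1R rose, ITGAM 1.98-fold (to 48.7 ± 2.04 CPM from 24.6 CPM) and CSF1R, the receptor for the macrophage growth factor, 2-fold (24.2 ± 0.654 CPM against 12.1 CPM). MLLT1 was 45.8 ± 0.141 CPM with sgENL1, 28.4 ± 0.38 CPM with sgENL5 and 47.5 CPM with sgGFP, a fall over both guides (log2 -0.40 (0.11), adjusted p = 0.0216). In all, 1733 genes were called, 1033 higher and 700 lower, and 74 rose and 40 fell by 2-fold or more.

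The complement gene CFP (2.54-fold), ALOX5AP of leukotriene synthesis (2.32-fold) and the transcription factor FOXO1 (2.17-fold, to 26 ± 2.45 CPM) led the rises at day 3. TNFRSF19 (2.72-fold), CYP2W1 (2.33-fold), DDN (1.96-fold) and CBS (1.88-fold) were among the falls. Cell cycle genes fell in 15 of 34 cases, 28 when adjusted over the list alone, and rose in 0 (median -0.22, adjusted p = 8.07e-15, or 0.112 with an estimated correlation). Of the MYC targets, 12 fell and 0 rose, 31 when adjusted over the list alone (median -0.19, adjusted p = 5.8e-14, or 0.196 with an estimated correlation). Stress response genes showed 9 falls and 0 rises of 22 (median -0.28, adjusted p = 1.33e-11, or 0.112 with an estimated correlation), with STC2 1.97-fold lower. Monocyte genes had 9 rises and 1 fall of 28, 12 rises when adjusted over the list alone (median 0.33, adjusted p = 3.46e-08, or 0.0974 with an estimated correlation). The p53 targets had 8 rises and 1 fall of 30, 14 rises over the list alone (median 0.21, adjusted p = 1.89e-06, or 0.0974 with an estimated correlation). The HOXA-MEIS1 program rose with 8 genes higher and 1 lower of 31 (median 0.11, adjusted p = 0.0141, or 0.4 with an estimated correlation), led by LMO2 (1.66-fold) and PBX3 (1.39-fold). Genes raised by BET inhibitors had 2 rises of 11 (adjusted p = 0.0048, or 0.196 with an estimated correlation), HEXIM1 among them (1.24-fold). Ribosomal protein genes rose as a list (median 0.14, adjusted p = 5.13e-06, or 0.49 with an estimated correlation), though only 3 rose and 1 fell. Sterol genes did not move (0 of 19 called, median -0.01, adjusted p = 0.858). With 1 control library the spread of that group cannot be seen, and a fit of only the groups compared called 3383 genes. The change of the ENL effect from day 3 to day 5 passed for 26 genes, 1 more positive and 25 more negative at day 5, among them GDF15, a stress-induced cytokine gene (log2 -2.10 (0.28), adjusted p = 0.000955), and MPO (log2 -0.79 (0.11), adjusted p = 0.000955).

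With the AF9 guide MYC was not called: its log2 change at day 5 was -0.09 (adjusted p = 0.571). MLLT3 RNA was 20.8 ± 2.12 CPM with sgAF9 and 19.2 ± 1.88 CPM with sgGFP at day 5 (n = 2 each, log2 0.11 (0.08), adjusted p = 0.64), and 18.4 ± 0.188 CPM against 17.7 CPM at day 3. The RNA therefore gives no measure of the AF9 knockout. Only 58 genes were called at day 5, 37 higher and 21 lower. Against sgGFP, GDF15 was 2.78-fold lower but stood at 0.896 CPM against 2.51 CPM. MPO was 1.48-fold lower at 40.5 ± 4.26 CPM, and ZNF367 was 1.42-fold higher (adjusted p = 0.00136). These 3 calls, of 22 named, were kept in every omission. From day 3 to day 5, MPO changed by log2 0.03 in sgAF9 and 0.57 in sgGFP cells, and GDF15 by 0.11 and 0.93. Their lower levels at day 5 therefore went with a rise in the control, whose day-3 level rests on 1 library.

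Among the lists that passed lower with sgAF9 at day 5, granulocyte precursor genes had the most called members. Of 13 genes 4 fell and 0 rose, 6 when adjusted over the list alone (median -0.19, adjusted p = 2.52e-12, or 0.099 with an estimated correlation). They included the granule protease genes PRTN3 (log2 -0.46), ELANE (-0.40) and CTSG (-0.33), whose calls were lost without sgAF9 replicate 1 or sgGFP replicate 2. Ribosomal protein genes were lower as a list with 0 genes called (median -0.12, adjusted p = 2.52e-12, or 0.668 with an estimated correlation). The p53 targets (1 fall of 30, adjusted p = 0.00973, or 0.444 with an estimated correlation), interferon genes (0 of 34, adjusted p = 0.00515, or 0.393 with an estimated correlation) and stress response genes (0 of 22, adjusted p = 0.0168, or 0.671 with an estimated correlation) were also lower. The elongation complexes were higher with 0 genes called of 26 (median 0.05, adjusted p = 0.0208, or 0.457 with an estimated correlation). The count of called genes was 4 without sgAF9 replicate 1, 490 without sgAF9 replicate 2, 19 without sgGFP replicate 1, 28 without sgGFP replicate 2, 155 with DESeq2 and 220 with no filter. At day 3, 0 genes were called with sgAF9 (0 with DESeq2), against 754 at an unadjusted p below 0.05, and the sterol list was higher (median 0.18, adjusted p = 3.8e-06, or 0.626 with an estimated correlation). The MYC target, monocyte, granulocyte, stress response and ribosomal protein lists also passed at the preset correlation and not with an estimated correlation, the largest adjusted p being 0.0452.

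Compared directly at day 5, the ENL guides left MYC 1.73-fold lower than the AF9 guide (log2 -0.79 (0.05), adjusted p = 8.66e-12, 215 ± 4.79 CPM against 373 CPM). MLLT1 was lower with the ENL guides (log2 -0.42, adjusted p = 0.00081), and MLLT3 was lower too (log2 -0.31, adjusted p = 0.00225), a call lost without sgAF9 replicate 1. Between the guides 4189 genes differed, 2106 higher and 2083 lower with the ENL guides. S100A8 was 2.42-fold higher, CFD, which encodes a complement protease, 2.13-fold higher (547 CPM against 257 CPM), and CDKN1A, the p53-induced cell cycle inhibitor, 1.43-fold higher. TNFRSF19 was 2.83-fold lower. By list, 19 of 34 cell cycle genes were lower and 0 higher (adjusted p = 1.38e-09, or 0.259 with an estimated correlation). So were 15 of 19 sterol genes (median -0.40, adjusted p = 2.74e-12, or 0.207 with an estimated correlation). The p53 targets had 15 genes higher and 0 lower of 30 (adjusted p = 1.39e-07, or 0.122 with an estimated correlation). Monocyte genes had 13 and 2 of 28 (adjusted p = 1.81e-06, or 0.122 with an estimated correlation), and granulocyte genes had 5 and 2 of 13 (adjusted p = 0.000886, or 0.279 with an estimated correlation), with ELANE at 1060 CPM against 633 CPM. Ribosomal protein genes were higher in 27 of 84 cases and lower in 1 (adjusted p = 6.49e-08, or 0.564 with an estimated correlation). Lower as lists were stress response genes (9 of 22, adjusted p = 0.000104, or 0.311 with an estimated correlation), MYC targets (12 of 52, with 1 higher, adjusted p = 0.00017, or 0.564 with an estimated correlation) and the elongation complexes (6 of 26, with 1 higher, adjusted p = 0.0112, or 0.279 with an estimated correlation). Without sgAF9 replicate 1 the count was 2532.

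The second knockout experiment, read at 4 days with an empty vector, again had lower MYC: 220 ± 18.6 CPM in sgENL cells and 375 ± 1.35 CPM in sgLuc cells (n = 2 each, 1.71-fold, log2 -0.77 (0.09), adjusted p = 0.00293). MPO fell 2.02-fold to 34.6 ± 1.91 CPM, and ITGAM rose 1.82-fold to 70.4 CPM from 38.7 CPM. MLLT1 was 30.9 ± 3.97 CPM against 48.9 ± 6.78 CPM, a 1.58-fold lower level that did not pass (log2 -0.66 (0.18), adjusted p = 0.0701). It did pass in the fit with a block per replicate number, the paired MLLT1 levels being 28.1 against 44.1 CPM in replicate 1 and 33.7 against 53.6 CPM in replicate 2. Cell cycle genes fell in 15 of 34 cases, or 28 when adjusted over the list alone, with 0 rises (median -0.36, adjusted p = 1.54e-21, and 0.0239 with an estimated correlation).

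In this comparison 843 genes were called, 457 higher and 386 lower. The fit with a block per replicate number called 4963, of which 2227 were higher and 2736 lower, so the larger side turned. SOCS3, a brake on cytokine signalling, rose 3.63-fold (log2 1.86 (0.25)), PHLDA1 2.65-fold, TP53INP2 2.34-fold and EPAS1 2.31-fold. TNFRSF19 fell 2.56-fold to 24.2 CPM from 61.9 CPM, DDN 2.45-fold and CCR2, a monocyte chemokine receptor gene, 2.38-fold to 18.9 CPM from 45.0 CPM. FOS (3.1-fold higher) and INSIG1 (2.05-fold lower) were called only while sgENL vector replicate 1 was in the fit. Sterol genes fell in 8 of 19 cases, 12 over the list alone, and rose in 0 (median -0.37, adjusted p = 2e-11, or 0.168 with an estimated correlation). Stress response genes had 9 falls and 2 rises of 22 (median -0.26, adjusted p = 4.35e-06, or 0.168 with an estimated correlation). MYC targets had 4 falls of 52, 8 over the list alone (median -0.18, adjusted p = 1.5e-08, or 0.288 with an estimated correlation). Rises were found in 4 of 25 monocyte genes, with 1 fall, or 12 and 3 over the list alone (median 0.38, adjusted p = 0.000855, or 0.288 with an estimated correlation). They were also found in 4 of 30 p53 targets (median 0.21, adjusted p = 1.53e-05, or 0.168 with an estimated correlation). The BET-raised genes had 1 rise of 11 (adjusted p = 0.00218, or 0.288 with an estimated correlation). The elongation complexes had 2 falls of 25 (adjusted p = 0.0421, or 0.366 with an estimated correlation). The count was 85 and 179 without sgENL vector replicate 1 and 2, 152 and 250 without sgLuc replicate 1 and 2, and 1312 with DESeq2. In all, 12 of 47 named calls were kept in every omission.

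Wild-type ENL raised MYC and MPO and lowered ITGAM. MYC rose 1.88-fold over the sgENL vector cells (log2 0.91 (0.09), adjusted p = 0.000191), to 414 ± 24.5 CPM from 220 ± 18.6 CPM, and MPO rose 2.93-fold to 101 CPM, while ITGAM fell 2.26-fold to 31.2 CPM. MLLT1 was 36.7 ± 7.08 CPM with the WT construct and 30.9 ± 3.97 CPM with the vector (log2 0.25, adjusted p = 0.423), a difference that passed with a block per replicate number (31.7 against 28.1 CPM and 41.7 against 33.7 CPM in the pairs). The monocyte genes LGALS3 (log2 -2.23) and CD86, which encodes a co-stimulatory receptor (-1.66), fell.

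In all, 2214 genes were called, 915 higher and 1299 lower, with 143 rises and 418 falls of 2-fold or more. With a block per replicate number 6662 were called, 3595 higher and 3067 lower, so the larger side turned. The pathogen receptor gene CD209 fell 8.05-fold (log2 -3.01 (0.19)) to 8.04 CPM from 64.6 CPM, MPEG1, a macrophage pore protein gene, 7.77-fold, FGL2 6.58-fold, the Src-family kinase gene FGR 4.98-fold and HLA-DRA 4.49-fold. GIPC3 rose 4.57-fold, MFAP4 3.63-fold (to 211 CPM) and HES1, a Notch target, 3.09-fold. By list, 12 of 25 monocyte genes fell and 2 rose, 16 falls over the list alone (median -0.44, adjusted p = 1.39e-11, or 0.0878 with an estimated correlation), with LYZ, which encodes lysozyme, 2.36-fold lower at 227 CPM. Cell cycle genes rose in 21 of 34 cases, 29 over the list alone, and fell in 0 (median 0.36, adjusted p = 2.68e-12, or 0.0838 with an estimated correlation), as for UHRF1 (1.6-fold). MYC targets rose in 13 of 52 cases, 21 over the list alone, and fell in 0 (median 0.29, adjusted p = 4.68e-09, or 0.388 with an estimated correlation). The p53 targets had 8 falls and 2 rises of 30 (median -0.20, adjusted p = 0.00242, or 0.291 with an estimated correlation). The BET-raised genes had 4 falls of 11 (median -0.53, adjusted p = 0.000121, or 0.291 with an estimated correlation). Stress response genes had 8 rises and 1 fall of 22 (median 0.25, adjusted p = 0.00883, or 0.388 with an estimated correlation), SLC7A11 among the rises (log2 1.06). Ribosomal protein genes were higher as a list with 0 called (median 0.23, adjusted p = 0.000844, or 0.762 with an estimated correlation). The count was 897 and 1027 without sgENL vector replicate 1 and 2, and 1042 without WT replicate 1, and 38 of 48 named calls were kept in every omission.

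Neither mutant raised MYC detectably in the fit without pairing. MYC was 241 ± 0.579 CPM with F59A (log2 0.13 (0.09), adjusted p = 0.757) and 231 ± 12.3 CPM with Y78A (log2 0.07 (0.09), adjusted p = 0.889), against 220 ± 18.6 CPM with the vector. In the pairs it stood slightly above the vector. Replicates 1 and 2 had 241 and 240 CPM with F59A, 222 and 240 CPM with Y78A, and 206 and 233 CPM with the vector. MLLT1 stood at 29.9 ± 4.66 CPM with F59A (log2 -0.05, adjusted p = 0.988) and 32.3 ± 5.04 CPM with Y78A (log2 0.07, adjusted p = 0.966). Neither level was called against the vector. The RNA therefore does not show whether the mutant constructs were expressed, or as highly as WT. Some genes did move: with F59A, the receptor gene CD38 fell to 19.2 CPM from 48.8 CPM and RARA, the retinoic acid receptor gene, to 37.8 CPM from 84.8 CPM.

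With F59A, 202 genes were called, 110 higher and 92 lower. With a block per replicate number 2169 were called, 1019 higher and 1150 lower, so the larger side turned. CCR2 rose 2.62-fold to 49.4 CPM and the complement gene C3 1.97-fold, while CD38 fell 2.55-fold and RARA 2.25-fold. HLA-DRA rose 2.17-fold, a call lost without F59A replicate 1 or sgENL vector replicate 2. Monocyte genes had 5 rises and 2 falls of 25 (median 0.14, adjusted p = 1.72e-05, or 0.365 with an estimated correlation). The HOXA-MEIS1 program had 1 fall of 31, 7 over the list alone (median -0.19, adjusted p = 3.4e-06, or 0.346 with an estimated correlation), and the BET-raised genes had 1 fall of 11 (adjusted p = 0.000654, or 0.502 with an estimated correlation). Sterol genes (median -0.08, adjusted p = 0.0248, or 0.609 with an estimated correlation) and ribosomal protein genes (median 0.22, adjusted p = 3.4e-06, or 0.661 with an estimated correlation) passed as lists with 0 genes called. The count was 37 and 44 without F59A replicate 1 and 2, the same 37 and 44 without sgENL vector replicate 1 and 2, 349 with DESeq2 and 440 with no filter. With Y78A, 226 genes were called, 84 higher and 142 lower, or 2336 with a block per replicate number (1098 higher and 1238 lower). SHISA2 rose 2.97-fold, NRN1 2.92-fold and the oxidase subunit gene NCF4 2.18-fold, while FGR fell 2.5-fold, CD38 2.35-fold and RARA 2.32-fold. With Y78A the BET-raised genes had 1 fall of 11, 4 over the list alone (median -0.50, adjusted p = 4.03e-06, or 0.235 with an estimated correlation). The p53 targets had 2 falls of 30 (median -0.10, adjusted p = 0.00193, or 0.235 with an estimated correlation), and the HOXA-MEIS1 program had 1 rise and 1 fall of 31 (median -0.17, adjusted p = 4e-04, or 0.235 with an estimated correlation). Cell cycle genes were higher with 0 called (median 0.14, adjusted p = 4.56e-05, or 0.235 with an estimated correlation), as were ribosomal protein genes (median 0.16, adjusted p = 0.000589, or 0.73 with an estimated correlation). Sterol genes were lower with 0 called (adjusted p = 0.00715, or 0.58 with an estimated correlation). The count was 57 and 56 without Y78A replicate 1 and 2, 46 and 63 without sgENL vector replicate 1 and 2, 396 with DESeq2 and 542 with no filter. The mutants shared the vector libraries, so they were compared with each other directly, and 27 genes differed.

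Cells with wild-type ENL differed from cells with the mutants in MYC and in many myeloid genes. MYC was 1.76-fold higher with WT (log2 0.81 (0.07), adjusted p = 0.000174, 414 ± 24.5 CPM against 236 CPM), MPO 2.32-fold higher and TNFRSF19 2.44-fold higher. MLLT1 did not pass (log2 0.24, adjusted p = 0.381) but did with a block per replicate number. WT stood above F59A and Y78A in each pair (31.7 against 26.6 and 28.7 CPM, and 41.7 against 33.2 and 35.9 CPM). The contrast therefore does not separate the change in ENL from the level of the construct. HLA-DRA was 7.91-fold lower (6.32 CPM against 51.1 CPM), LYZ 3.42-fold lower (227 CPM against 791 CPM) and S100A9 3.79-fold lower (20.9 CPM against 81.3 CPM).

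Between WT and the mutants 1837 genes were called, 778 higher and 1059 lower with WT. With a block per replicate number 6059 were called, 3316 higher and 2743 lower, so the larger side turned. Monocyte genes were lower in 17 of 25 cases and higher in 1 (median -0.79, adjusted p = 3.62e-20, or 0.0502 with an estimated correlation), with CD86 at log2 -2.25 and ITGAM 1.86-fold lower. Cell cycle genes were higher in 14 of 34 cases and lower in 0, 24 over the list alone (median 0.27, adjusted p = 2.65e-10, or 0.0651 with an estimated correlation). MYC targets were higher in 12 of 52 cases and lower in 0, 27 over the list alone (median 0.24, adjusted p = 1.02e-09, or 0.373 with an estimated correlation). Sterol genes were higher in 5 of 19 cases (adjusted p = 3.09e-05, or 0.373 with an estimated correlation), SQLE at log2 0.75. Granulocyte genes were higher in 3 of 13 and lower in 1 (adjusted p = 0.0081, or 0.373 with an estimated correlation). Without WT replicate 1 or 2 the count was 726 or 963, without Y78A replicate 1 or 2 it was 1117 or 1019, and 27 of 42 named calls were kept in every omission.

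Treated with DMSO, sgENL cells had 1.47-fold less MYC than sgGFP cells (345 ± 7.66 CPM against 508 ± 11.8 CPM, n = 2 each, log2 -0.56 (0.09), adjusted p = 0.0156). MPO fell 2.69-fold, to 30.3 ± 0.251 CPM from 81.5 ± 0.351 CPM (adjusted p = 0.000662), and ITGAM rose 2.01-fold to 85.1 CPM from 42.4 CPM. MLLT1 was 36.8 ± 0.12 CPM against 57.2 ± 2.81 CPM, a 1.56-fold lower level that did not pass (adjusted p = 0.216). Its levels did not overlap between the groups (36.7 and 36.9 against 55.2 and 59.2 CPM). The fit also takes its spread from the sgGFP JQ1 libraries, which stood at 30.6 and 57.3 CPM. In all, 373 genes were called, 294 higher and 79 lower.

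The guidance receptor gene SEMA6A (2.97-fold) and ALOX5AP (2.36-fold) were among the largest rises in DMSO, and TNFRSF19 fell 3.57-fold to 10.9 CPM from 38.9 CPM. Monocyte genes had 5 rises and 2 falls of 24, 9 rises over the list alone (median 0.23, adjusted p = 0.000476, or 0.207 with an estimated correlation). The HOXA-MEIS1 program had 4 rises and 1 fall of 31, 9 rises over the list alone (median 0.14, adjusted p = 0.0133, or 0.449 with an estimated correlation), LMO2 at log2 0.57. Stress response genes had 3 falls of 22 (median -0.17, adjusted p = 5.14e-06, or 0.275 with an estimated correlation). BET-raised genes had 1 rise of 11 (median 0.40, adjusted p = 0.00447, or 0.275 with an estimated correlation). MYC targets (median -0.18, adjusted p = 1.13e-08, or 0.227 with an estimated correlation) were lower as a list with 0 genes called. So were cell cycle genes (median -0.24, adjusted p = 5.05e-09, or 0.32 with an estimated correlation). Granulocyte genes had 1 rise and 3 falls of 13, with a median of 0.10, a mean of -0.06 and a test direction down (adjusted p = 0.0279, or 0.533 with an estimated correlation). CTSG (log2 -0.84) and MS4A3 (-0.78) were among the falls. Leaving out sgENL DMSO replicate 1 or 2 left 5 or 2 calls, and leaving out sgGFP DMSO replicate 1 or 2 left 4 or 1. MPO was the only named call of 35 kept each time. The count was 612 with DESeq2, 864 with no filter and 4667 in a fit of only these groups. The full fit and the omissions above kept both sgGFP JQ1 libraries, the pair that differed most in the batch. Its chi-square per degree of freedom was 169, against 3.43 to 5.67 for the other pairs of the batch.

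JQ1 lowered the chemokine receptor gene CCR2 12.2-fold in sgGFP cells (7.42 CPM against 90.4 CPM) and MPO 9.09-fold (8.95 ± 0.495 CPM against 81.5 ± 0.351 CPM, n = 2 each). HEXIM1, an inhibitor of the elongation factor P-TEFb whose rise marks BET inhibition, rose 1.94-fold to 90 ± 0.373 CPM (log2 0.96 (0.08), adjusted p = 0.000266). MYC fell 1.4-fold to 364 CPM (adjusted p = 0.00622), a call lost without sgGFP DMSO replicate 1. MLLT1 was not called (log2 -0.38, adjusted p = 0.293), and its level in the library labelled sgGFP JQ1 replicate 1, 30.6 CPM, went against that label, being close to the 28.8 ± 1.99 CPM of sgENL JQ1 cells rather than the 57.3 CPM of replicate 2. MYC (360 CPM, against 368 CPM in replicate 2 and 163 and 169 CPM in sgENL JQ1 libraries) and ITGAM (67 CPM, against 70.1 CPM and 135 and 141 CPM) ran the way the label says.

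JQ1 changed 2887 genes in sgGFP cells, 1607 higher and 1280 lower, with 408 rises and 306 falls of 2-fold or more. TP53I3 rose 4.32-fold, CDKN1A 1.78-fold, and MPEG1 (log2 -2.48) and CD36 (3.99-fold) fell. Monocyte genes as a list did not pass, with 6 rises and 2 falls of 24 (adjusted p = 0.444). BET-raised genes rose in 8 of 11 cases, 10 over the list alone (median 1.10, adjusted p = 1.68e-11, and 0.046 with an estimated correlation), HIST1H2AC by 3.82-fold. MYC targets fell in 17 of 52 cases and rose in 0, 22 over the list alone (median -0.28, adjusted p = 4.24e-07, or 0.233 with an estimated correlation). Cell cycle genes fell in 13 of 34, 22 over the list alone (median -0.37, adjusted p = 3.43e-07, or 0.348 with an estimated correlation). Stress response genes fell in 13 of 22, with 1 rise (median -0.38, adjusted p = 2.28e-05, or 0.331 with an estimated correlation), SLC7A11 at log2 -2.09. Interferon genes rose in 11 of 34 cases and fell in 3 (median 0.39, adjusted p = 0.0134, or 0.348 with an estimated correlation). The p53 targets rose in 8 and fell in 3 of 30 (median 0.09, adjusted p = 0.00136, or 0.135 with an estimated correlation). Granulocyte genes split, 4 higher and 5 lower of 13 (median -0.01, adjusted p = 0.000689, or 0.348 with an estimated correlation), MS4A3 falling by log2 -1.96. The count was 782 without sgGFP DMSO replicate 1, with a similar drop without replicate 2. It was 6154 without the library labelled sgGFP JQ1 replicate 1, 8317 without replicate 2 and 690 in a fit of only these groups.

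In sgENL cells JQ1 lowered MYC 2.08-fold, to 166 ± 4.75 CPM from 345 ± 7.66 CPM (log2 -1.05 (0.09), adjusted p = 0.000108), and MPO 16.7-fold to 1.8 CPM. MLLT1 was not called (log2 -0.35, adjusted p = 0.296). TERT, the telomerase gene, fell 8.23-fold and CCR2 12.7-fold. All 52 MYC targets were called lower (list adjusted p = 0.0514 with an estimated correlation), as were all 34 cell cycle genes (list adjusted p = 0.103 with an estimated correlation). HEXIM1 rose 1.77-fold, TP53INP2 4.95-fold and ITGAM to 138 CPM from 85.1 CPM.

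There were 4970 called genes, 2201 higher and 2769 lower. The median change was log2 -0.72 for MYC targets (adjusted p = 3.08e-30 at the preset correlation) and -0.85 for cell cycle genes (adjusted p = 9.16e-25), with CDT1, a replication licensing gene, at -1.09 and E2F1 at -1.18. Rises were seen in 9 of 11 BET-raised genes (median 1.08, adjusted p = 5.69e-10, or 0.0876 with an estimated correlation) and in 14 of 31 HOXA-MEIS1 genes, with 2 falls (median 0.35, adjusted p = 0.000242, or 0.165 with an estimated correlation). Interferon genes rose in 12 of 34 cases, with 3 falls (median 0.26, adjusted p = 0.00107, or 0.127 with an estimated correlation). Stress response genes fell in 16 of 22 cases and rose in 3 (median -0.58, adjusted p = 1.25e-07, or 0.127 with an estimated correlation). Granulocyte genes fell in 6 of 13 and rose in 1 (median -0.85, adjusted p = 9.73e-10, or 0.117 with an estimated correlation). The p53 targets had 10 rises and 5 falls of 30 (adjusted p = 0.00404, or 0.103 with an estimated correlation). Ribosomal protein genes had 7 falls of 83 (median -0.27, adjusted p = 0.00196, or 0.839 with an estimated correlation). Without sgENL DMSO replicate 1 or 2 the count was 2155 or 1963, without sgENL JQ1 replicate 1 or 2 it was 2480 or 1812, and 9387 in a fit of only these groups.

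The effect of JQ1 differed between sgENL and sgGFP cells for 38 genes, 5 with a more positive and 33 with a more negative effect in sgENL cells, against 2580 at an unadjusted p below 0.05. PRTN3 changed by log2 0.34 with JQ1 in sgGFP cells and -1.46 in sgENL cells (adjusted p = 0.00576 for the difference). TERT (difference -1.86), FGR (-1.49), the amino acid transporter gene SLC38A5 (-1.41) and CDT1 (-0.91) also passed, and on the positive side TP53INP2 (1.09) and GBP2 (0.97). MYC (log2 -0.57 (0.12), adjusted p = 0.0809) and MLLT1 (0.03) did not. As lists, the MYC targets fell further in sgENL cells (median -0.48, adjusted p = 9.44e-24, or 0.0738 with an estimated correlation) with 0 of 52 genes called and 35 lower over the list alone. Cell cycle genes did so with 1 of 34 called and 20 over the list alone (median -0.47, adjusted p = 1.34e-16, or 0.21 with an estimated correlation). Granulocyte genes had 2 lower of 13, 6 over the list alone (median -0.52, adjusted p = 5.85e-08, or 0.21 with an estimated correlation). The HOXA-MEIS1 program had 1 higher of 31 (median 0.26, adjusted p = 1.75e-05, or 0.21 with an estimated correlation). Ribosomal protein genes (median -0.35, adjusted p = 3.22e-05, or 0.756 with an estimated correlation) and stress response genes (median -0.25, adjusted p = 0.018, or 0.719 with an estimated correlation) were lower with 0 called. The ribosomal protein median turned to 0.06 without the library labelled sgGFP JQ1 replicate 1. Without the library labelled sgGFP JQ1 replicate 1, 2198 genes were called, 1530 of them lower and all 38 kept. Without replicate 2 of that group it was 6646, 3455 lower, with all 38 kept, and without any 1 of the other 6 libraries it was 0. The count was 455 with DESeq2, 736 with no filter and 19 with RLE scaling, and 0 of 17 named calls were kept in every omission.

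In MV4;11 cells the hairpin lowered MLLT1 4.25-fold, to 22.1 ± 1.68 CPM from 94.0 ± 12.9 CPM (n = 3 each, log2 -2.09 (0.12), adjusted p = 4.13e-05). MYC fell 1.33-fold, to 539 ± 43.2 CPM from 718 ± 57.3 CPM (adjusted p = 0.011), and the leukaemia program genes HOXA10 (2.9-fold, to 16.6 CPM from 48 CPM), HOXA9 (2.03-fold, to 23.6 CPM from 47.9 CPM) and MEIS1 (1.42-fold) fell with it. The antigen presentation gene HLA-DRA rose 28.5-fold, to 685 ± 33.4 CPM from 24 ± 5.05 CPM, and its activator CIITA 8.26-fold. ITGAM rose 6.85-fold to 20.3 CPM from 2.96 CPM.

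The hairpin changed 4983 genes, 2512 higher and 2471 lower, with 807 rises and 479 falls of 2-fold or more. IGF1, a growth factor gene, rose 26.4-fold and the lipase gene AOAH by log2 3.48, while CTSG fell 5.98-fold and MPO 2.02-fold. Monocyte genes rose in 13 of 26 cases and fell in 2 (median 0.52, adjusted p = 1.49e-10, and 0.0269 with an estimated correlation), with CD36 5.23-fold higher (from 22 CPM in shNT cells) and CSF1R 2.78-fold higher (148 CPM against 53.3 CPM). Interferon genes rose in 17 of 33 and fell in 2 (median 0.57, adjusted p = 0.000149, or 0.426 with an estimated correlation), IFI6 among them. Rises were also found in 56 of 84 ribosomal protein genes, with 1 fall (median 0.26, adjusted p = 6.06e-09, or 0.426 with an estimated correlation), and in 6 of 11 BET-raised genes, with 1 fall (median 0.70, adjusted p = 2.02e-05, or 0.426 with an estimated correlation). Of 31 p53 targets 7 rose and 1 fell (median 0.06, adjusted p = 0.0484, or 0.426 with an estimated correlation).

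Cell cycle genes fell in 29 of 34 cases in MV4;11 (median -0.58, adjusted p = 7.8e-15, or 0.426 with an estimated correlation), and MYC targets in 33 of 52 (median -0.42, adjusted p = 5.38e-10, or 0.426 with an estimated correlation), each with 0 rises. Sterol genes fell in 8 of 19 (median -0.49, adjusted p = 0.000149, or 0.426 with an estimated correlation), with 0 rises and DHCR7 at log2 -1.92. The HOXA-MEIS1 program had 10 falls and 2 rises of 25, 13 and 3 over the list alone (median -0.23, adjusted p = 0.000502, or 0.426 with an estimated correlation). Stress response genes had 7 falls of 20, 11 over the list alone (median -1.38, adjusted p = 0.00232, or 0.535 with an estimated correlation), PHGDH standing at 25.6 ± 6.2 CPM against 265 ± 313 CPM. Without shNT replicate 1 the median was -0.57, PHGDH moved from log2 -3.38 to -1.75 and TRIB3 from -3.33 to -1.37. Erythroid genes had 3 falls of 4 (adjusted p = 0.00966, or 0.426 with an estimated correlation) and granulocyte genes 4 falls of 14 (adjusted p = 0.0217, or 0.426 with an estimated correlation). The count was 2593 and 2876 without shENL replicate 1 and 2, and 56 of 71 named calls were kept in every omission. PHGDH, TRIB3 and PSAT1 (log2 -2.25) were lost without each shENL library.

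**Figure D2:**
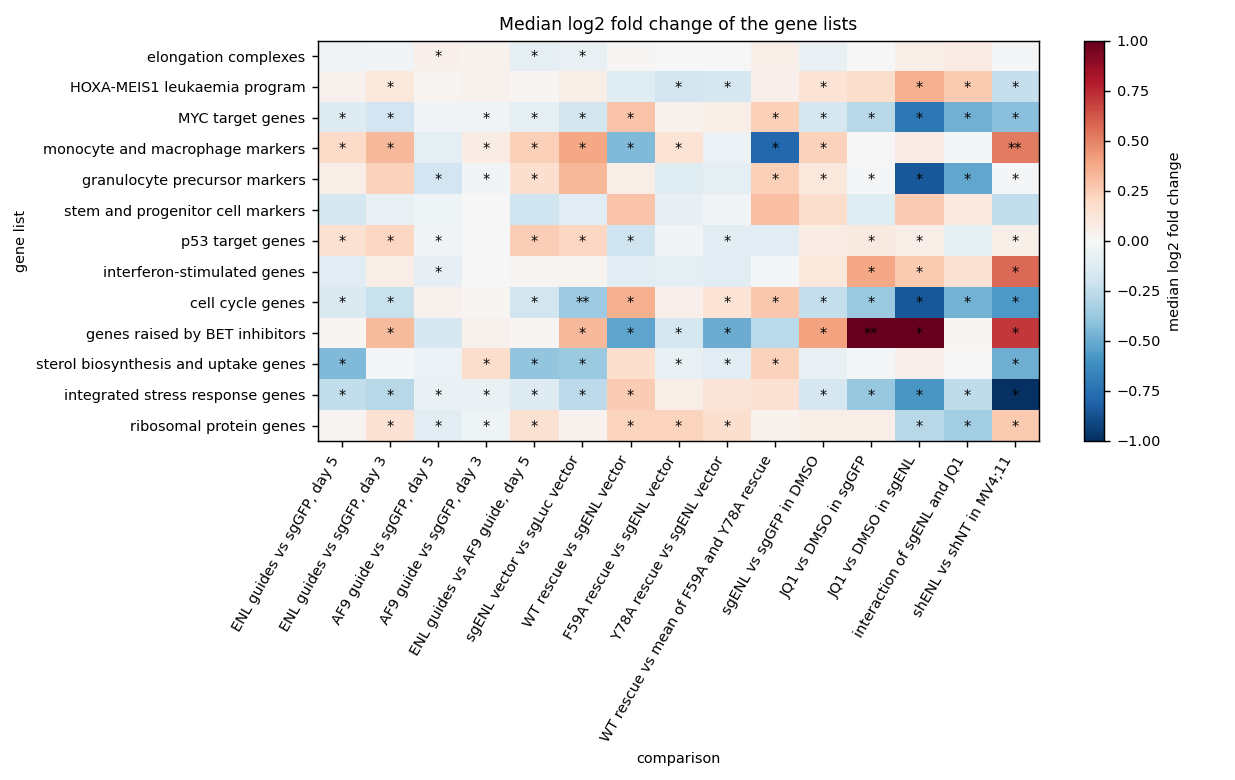
Each cell is the median log2 fold change of a gene list (vertical axis) in a comparison (horizontal axis), coloured from -1 to 1. A star marks an adjusted p of 0.05 or less at the preset correlation, and 2 stars the 3 tests that passed with an estimated correlation as well, such as the cell cycle list of sgENL vector cells (median -0.36).

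Across the 4 ENL-loss comparisons (day 5, vector, DMSO and MV4;11, with no library in common), 15 genes were lower in every case where 0.0223 were expected by chance, and 46 were higher where 0.121 were expected, of 14776 genes tested in all. The lower genes numbered 51 with DESeq2 and 49 with no filter, and the DMSO calls that limit both counts, 373, fell to between 1 and 5 when any 1 of their 4 libraries was left out. The lower genes included MYC, MPO, CTSG, CBS, DDN, SLC38A5 and GPT2, and the higher ones ITGAM, CSF1R, CD36, CFP, NFE2, GRN, PSAP, CD82 and PHLDA1, with NCF1 and HIST1H2BK among those that may share reads with copies. Within MOLM-13 alone, 40 genes were lower in all 3 batches (0.145 expected) and 137 higher (0.814 expected). Of the genes called in both day 5 and the vector batch, 99.5% of 597 had the same sign, with 275 lower in both (36.8 expected, p = 1.07e-196 by Fisher's exact test) and 319 higher in both (44.4 expected). Against MV4;11, day 5 shared 487 lower (216 expected) and 418 higher genes (221 expected), and 74.6% of 1213 had the same sign.

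**Figure D3:**
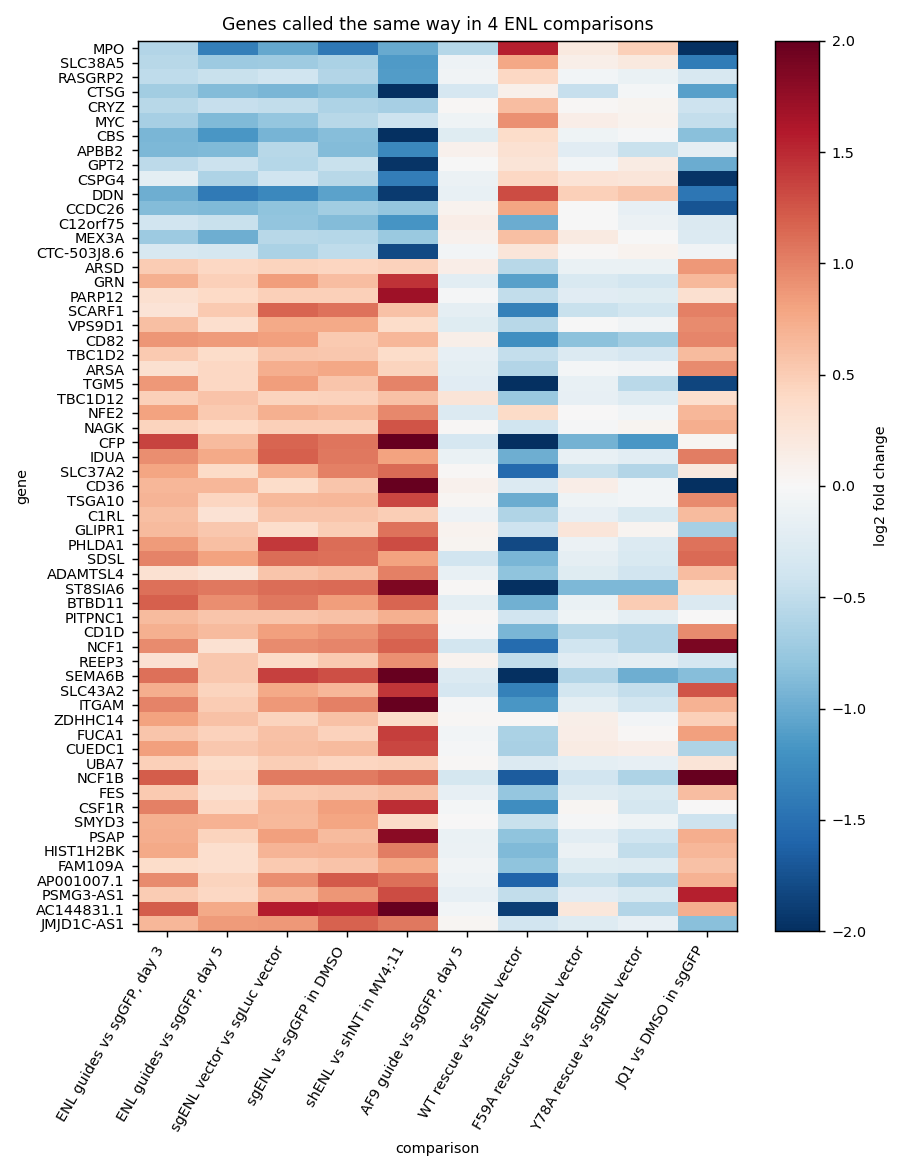
The vertical axis lists the 15 lower and 46 higher genes and the horizontal axis the comparisons, with colour for the log2 fold change from -2 to 2. MYC, among the lower genes, stood at -0.89 at day 5 with the ENL guides.

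Genes picked from the other batches also showed the rescue. Of the 18 lower and 66 higher genes common to day 5, DMSO and MV4;11, WT raised 14 and lowered 2 of the former (median log2 0.51) and lowered 50 and raised 1 of the latter (median -0.75). F59A raised 0 of the lower genes (median 0.02) and lowered 4 of the higher ones, raising 2 (median -0.16). Y78A raised 2 of the lower genes (median 0.02) and lowered 10 of the higher ones, raising 2 (median -0.26). In the direct contrast, WT stood above the mutants in 11 and below in 2 of the 18, and below in 45 and above in 2 of the 66. All these counts come from the fit without pairing and were not redone with a block per replicate number. With the block, calls over all genes went from 202 to 2169 for F59A, 226 to 2336 for Y78A and 2214 to 6662 for WT. Low mutant counts therefore do not show that the mutants left these genes unchanged. The larger sets called at day 5 were tested as well. For the lower set of 1533 measured genes the median was 0.24 with WT (adjusted p = 0.0119 with an estimated correlation), 0.05 with F59A (adjusted p = 0.00322, or 0.133 with an estimated correlation) and 0.07 with Y78A (adjusted p = 0.000706, or 0.103 with an estimated correlation). For the higher set of 1565 genes it was -0.25 with WT (adjusted p = 0.00812 with an estimated correlation), -0.06 with F59A (adjusted p = 9.16e-06, or 0.0729 with an estimated correlation) and -0.07 with Y78A (adjusted p = 0.0312 with an estimated correlation), where 59 genes fell and 11 rose. Comparisons with sgLuc cells were chosen after seeing the data. Against sgLuc, the median of the lower set was -0.02 with WT, -0.21 with F59A and -0.19 with Y78A. WT cells still differed from sgLuc cells, with 331 genes higher and 607 lower. In the lower set 52 genes were higher and 128 lower. HLA-DRA stood at 6.36 and 6.27 CPM with WT and at 24.4 and 19.7 CPM with sgLuc. The changes with WT were therefore not only a return to the control.

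**Figure D4:**
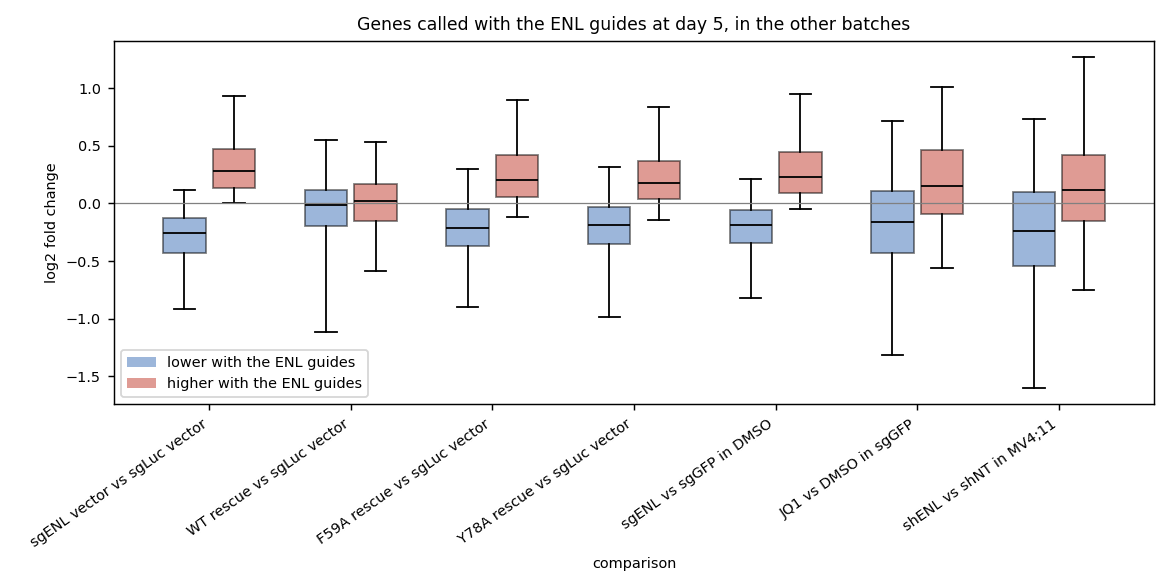
Boxes show log2 fold changes (vertical axis) of the genes lower (blue) or higher (red) with the ENL guides at day 5, in 7 comparisons of other batches (horizontal axis), as quartiles with whiskers from the 5th to the 95th percentile. The lower set had a median of -0.26 in sgENL vector cells and -0.24 in MV4;11.

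JQ1 in sgGFP cells shared 348 lower genes with ENL loss at day 5 (120 expected, p = 3.66e-84 by Fisher's exact test) and 369 higher genes (154 expected, p = 1.05e-64 by Fisher's exact test). Of the 934 genes called in both, 76.8% had the same sign. Those that fell with both included MYC, MPO, CBS, CTSG and SLC38A5. MLLT1 in the library labelled sgGFP JQ1 replicate 1 was 30.6 CPM, against its label. It was 57.3 CPM in replicate 2, and 27.4 and 30.2 CPM in sgENL cells with JQ1. MYC and ITGAM in that library ran with the label. The overlap was not repeated without that library, so its share in the overlap is not known. The lower day-5 set had a median of -0.16 with JQ1 in sgGFP cells (adjusted p = 0.0607 with an estimated correlation), -0.30 with JQ1 in sgENL cells (adjusted p = 0.0425 with an estimated correlation) and -0.51 with sgENL and JQ1 together against sgGFP cells in DMSO (adjusted p = 0.0177 with an estimated correlation). MYC levels over these groups were 508 ± 11.8 CPM, 364 CPM with JQ1, 345 ± 7.66 CPM with sgENL and 166 ± 4.75 CPM with both.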

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

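The test of JQ1 effects by length-matched lists and the regrouping of MV4;11 libraries were chosen before the results were seen, and the other tests here only after.

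The results in this paragraph are listed because an effect differed between groups. The effect of JQ1 differed between sgENL and sgGFP cells for 38 genes. The effect of the ENL guides differed between day 3 and day 5 for 26 genes, a test that rests on the only sgGFP library of day 3. MEIS1 and MYB fell in MV4;11, while at day 5 in MOLM-13 MYB rose slightly and MEIS1 did not pass, the change in MV4;11 less that in MOLM-13 being log2 -0.63 for MEIS1 and -0.56 for MYB. These last differences were not tested, and the lines also differ in how ENL was lowered and for how long.

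MYC targets fell further with JQ1 in sgENL cells than in sgGFP cells (median -0.48, adjusted p = 0.0738 with an estimated correlation, 0 of 52 genes called). The library labelled sgGFP JQ1 replicate 1 stood apart, with 8.73% mitochondrial counts. Its MLLT1 level went against its label, while its MYC (360 CPM) and ITGAM (67 CPM) ran with the label. It differed from replicate 2 in other panel genes too. CDK6 (217 against 323 CPM) and BCL2 (59.8 against 89.4 CPM) were lower, and HOXA9 (88.8 against 74.2 CPM) was higher. Without the library labelled sgGFP JQ1 replicate 1 the list median was -0.45, which argues against that library as the source. Of 10000 random lists matched on exon length and expression, a share of 0 lay as low as the list, the lowest having a median of -0.28. Whether the size of the difference holds in other cultures stays open, since 1 treated sgGFP library remains.

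Integrated stress response genes were lower with shENL in MV4;11 (median -1.38, adjusted p = 0.535 with an estimated correlation), where shNT replicate 1 had the highest levels of these genes. Without that library the median was -0.57, with 11 of 20 genes lower and 1 higher, so the library may account for part of the size but not for the direction. The list was also lower in 3 of the 3 MOLM-13 ENL comparisons at the preset correlation, as an effect of ENL loss would give. With an estimated correlation it passed in 0 (adjusted p = 0.144, 0.168 and 0.275). At the preset correlation the list was lower as well with the AF9 guide at day 5 and with JQ1 in sgGFP cells. By the labels, ENL was not targeted there. Neither of these passed with an estimated correlation. At the preset correlation, a lower list was therefore not particular to ENL loss. What set shNT replicate 1 apart stays open.

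Sterol genes were lower with the ENL guides at day 5 (median -0.44) and not at day 3 (median -0.01). The day-3 value rests on 1 sgGFP library, so an effect of the same size at both days is not excluded. The same genes rose from day 3 to day 5 by 0.39 in sgAF9 cells, by 0.69 in sgGFP cells and by 0.15 with the ENL guides. The day-5 difference may therefore hold a rise in control cultures that cells with the ENL guides shared to a smaller extent. What set that rise stays open. At day 5 the list was also lower against sgAF9 cells (median -0.4), which had the rise too. At the preset correlation it was lower in sgENL vector cells against sgLuc cells and with shENL against shNT. These comparisons used other controls, so the rise in sgGFP and sgAF9 cultures does not enter them. With an estimated correlation the list did not pass in any of them. The list was tested in DMSO as well, but that result is not given here. A lower sterol list is therefore not shown for every ENL comparison.

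In MV4;11, 4983 genes were called between shENL and shNT, 1 of 10 ways to split the 6 libraries into equal groups reached this, and the highest count of the other ways was 0. With 10 splits no share under 0.05 can be reached.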

How the results depend on the processing

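Counts of called genes depended on the method chosen. With no filter on low counts the count was 220 for the AF9 guide at day 5 (58 with the filter), 5 for the AF9 guide at day 3 (0), 1372 for the sgENL vector (843), 440 for F59A (202), 542 for Y78A (226), 864 for sgENL in DMSO (373) and 736 for the interaction (38). With DESeq2 it was 155 for the AF9 guide at day 5, 1312 for the sgENL vector, 349 for F59A, 396 for Y78A, 612 for sgENL in DMSO and 455 for the interaction. A fit of only the groups compared gave 3383 for the ENL guides at day 3 (1733), 4 for the AF9 guide at day 3, 204 for the sgENL vector, 1231 for WT (2214), 71 for F59A, 4667 for sgENL in DMSO, 690 for JQ1 in sgGFP cells (2887) and 9387 for JQ1 in sgENL cells (4970). With RLE scaling the interaction gave 19, and with sgENL1 alone day 5 gave 1921 (3158). The genes lower or higher in all 4 ENL comparisons were 15 and 46, and the lower ones numbered 51 with DESeq2 and 49 with no filter. The overlap of ENL-lower gene sets, day 5 and DMSO, held 67 genes, or 153 with DESeq2 and 213 with no filter. The cause of these differences was not tested.

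With a block per replicate number, the paired fit gave 4963 for the sgENL vector, 6662 for WT, 2169 for F59A, 2336 for Y78A and 6059 for WT against the mutants. In batch 3, whose numbers did not pair libraries, it gave 133 for sgENL in DMSO and 3 for the interaction.

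The share of calls that were lower moved by more than 10 points under these alternatives. Without the filter it was 24.8% at day 3 with the ENL guides (40.4% with it), 52.3% with the AF9 guide at day 5 (36.2%), 32.4% with the sgENL vector (45.8%) and 31.7% in DMSO (21.2%). In a fit of only the groups compared it was 49.5% in DMSO and 69.1% with WT (58.7%). For the interaction it was 73.7% with RLE scaling (86.8%). With the block per replicate number it was 46% for WT, 45.3% for WT against the mutants (57.6%) and 100% for the interaction. Leaving out 1 library also moved it. It was 52.2% to 75% for the AF9 guide at day 5 (without either sgAF9 library or sgGFP replicate 1), 30.3% to 34.1% for the sgENL vector (without sgLuc replicate 1 or either vector library), and 70.1% and 69.4% for WT (without vector replicate 1 or WT replicate 1). It was 61.4% for F59A (45.5% with all libraries, without vector replicate 2), 43.9% for Y78A (62.8%, without Y78A replicate 1), and 67.7% to 70.1% for WT against the mutants (without either WT library or Y78A replicate 1). It was 69.6% and 52% for the interaction (without the library labelled sgGFP JQ1 replicate 1, or without replicate 2). In DMSO, omissions left 1 to 5 calls, too few for a share. The cause was not tested. On simulated changes of 1.5-fold, 8.96% were found in the interaction and 98.5% at day 5 with the ENL guides.

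List tests depended on the correlation used: 107 of 240 passed at the preset correlation and 3 with an estimated correlation. Among sets from day 5, the lower set had a median of 0.05 with F59A and 0.07 with Y78A, and each passed at the preset correlation but not with an estimated correlation. The higher set with Y78A passed with both. Of 240 list readings, 213 kept their result with no filter, 238 with RLE scaling and 231 with a block per replicate number, and of 1120 with 1 library left out 1036 did. Of 749 named-gene readings, 731 kept their result with DESeq2, 742 with RLE scaling, 717 with no filter and 678 with a block per replicate number.

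Leaving out 1 library gave these lowest and highest counts: 0 and 0 for the AF9 guide at day 3, 4 and 490 at day 5, 2532 and 4123 for ENL against AF9 guides, 1242 and 1380 for the ENL guides at day 3, and 1500 and 3102 at day 5. In batch 2 they were 85 and 250 for the sgENL vector, 897 and 1440 for WT, 37 and 44 for F59A, 46 and 63 for Y78A, and 726 and 1284 for WT against the mutants. In batch 3 they were 1 and 5 for sgENL in DMSO, 782 and 8317 for JQ1 in sgGFP cells, 1812 and 2480 for JQ1 in sgENL cells, and 0 and 6646 for the interaction. In MV4;11 they were 2593 and 6988. Both high counts of JQ1 in sgGFP cells and the interaction came from leaving out 1 of the sgGFP JQ1 libraries, which differed from each other. Of 3592 named-gene readings with 1 library left out, 2912 kept their result, 654 were weaker, 25 stronger and 1 reversed. The reversed reading was MLLT1 in the interaction, 0.03 with all libraries, -0.32 without the library labelled sgGFP JQ1 replicate 1 and 0.56 without replicate 2. The ribosomal protein list reversed 4 times. In the vector comparison its median was 0.03, but -0.16 without sgLuc replicate 2 and -0.12 without sgENL vector replicate 1, the highest value being 0.25 without sgLuc replicate 1. In the interaction it was -0.35, but 0.06 without the library labelled sgGFP JQ1 replicate 1 and -0.64 without replicate 2. With JQ1 in sgGFP cells it was 0.07, but -0.33 without the library labelled sgGFP JQ1 replicate 1 and 0.35 without replicate 2. The cause was not tested.

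The only sgGFP library of day 3 could not be left out. A fit of only the groups compared is the same as the fit used for the interaction and for MV4;11, and so adds nothing there. A group cut to 1 library by an omission was assumed to vary like the others.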

Other observations

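Genes of the MHC class II pathway, a list chosen after seeing the data, moved most between the rescue constructs. WT lowered 10 of 12 (median log2 -1.93, adjusted p = 0.00779 with an estimated correlation), F59A raised 7 of 12 (median 0.91, adjusted p = 0.00761 with an estimated correlation) and Y78A changed 0 (median 0.39, adjusted p = 0.000834, or 0.19 with an estimated correlation). Compared directly, F59A stood above Y78A as a list (median 0.58, adjusted p = 0.00761 with an estimated correlation), with 0 of 12 genes called. WT stood below the mutants for 11 of 12 (median -2.57, adjusted p = 0.00535 with an estimated correlation). Relative to sgLuc cells, 9 were lower with WT (median -1.72), 8 higher with F59A (median 1.12) and 4 higher with Y78A (median 0.60). With an estimated correlation the adjusted p was 0.00761 for WT and for F59A, and 0.0866 for Y78A. In MV4;11, 12 of 13 rose with shENL (median 3.44, adjusted p = 0.00761 with an estimated correlation), while at day 5 the ENL guides raised 1 and lowered 1 (median 0.16). In the other MOLM-13 comparisons of ENL guides the median was 0.37 at day 3, against 1 sgGFP library, 0.12 with the vector and -0.13 in DMSO. JQ1 lowered 8 of 11 in sgGFP cells (median -0.88, adjusted p = 0.2 with an estimated correlation). Reads may be shared between these near-identical genes.

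Hypoxia and glycolysis genes, also chosen after seeing the data, were lower in 15 of 30 cases with the ENL guides at day 5 (median -0.36, adjusted p = 0.303 with an estimated correlation) and not at day 3 (median 0.06). From day 3 to day 5 genes of the list rose in sgGFP cells (21 genes, median 0.67, adjusted p = 0.2 with an estimated correlation), in sgAF9 cells (18 genes, median 0.46, adjusted p = 0.268 with an estimated correlation) and with the ENL guides (17 genes, median 0.35, adjusted p = 0.394 with an estimated correlation). Immediate early genes rose in 7 of 24 cases in sgENL vector cells (median 0.47, adjusted p = 0.303 with an estimated correlation). With the ENL guides at day 5 they went the other way, 10 lower and 1 higher of 25 (median -0.20, adjusted p = 0.000164, or 0.303 with an estimated correlation), and in DMSO 0 of 24 were called (median -0.02). From day 3 to day 5 these genes also rose in control cultures: 14 rose and 1 fell in sgGFP cells (median 0.56, adjusted p = 0.0518 with an estimated correlation), and 16 rose in sgAF9 cells (median 0.68, adjusted p = 0.0147 with an estimated correlation). With the ENL guides 14 rose and 2 fell (median 0.43, adjusted p = 0.0528 with an estimated correlation). With JQ1, 14 of 24 rose in sgGFP cells (median 1.02, adjusted p = 0.2 with an estimated correlation), and in sgENL cells 18 rose and 2 fell (median 0.75, adjusted p = 0.303 with an estimated correlation).

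Mitochondrial genes took 1.71% to 3.1% of counts in batch 1, 2.46% to 4.72% in batch 2 and 3.63% to 8.73% in batch 3, the highest being the library labelled sgGFP JQ1 replicate 1. The MV4;11 table does not hold the 37 mitochondrial genes of the other tables, and 3 mitochondrial pseudogenes took 0.302% to 0.488% there. Levels in MV4;11 are therefore scaled to a total without mitochondrial genes. Ribosomal protein genes took 13.4% of counts in the library labelled sgGFP JQ1 replicate 1 and 9.24% in replicate 2.

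Between day 5 and day 3 after doxycycline, 4586 genes differed in sgAF9 cells (2 against 2 libraries), 3525 in sgGFP cells (2 against 1) and 6232 with the ENL guides (4 against 4). Time in culture and time of Cas9 induction were not separated.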
